A study of Homo sapiens with 22 samples.

How the data were processed

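The data were expression values of 22 arrays of 8 human prostate cancer xenograft lines, hybridised with labelled total RNA on a 3' expression array of 54675 probe sets. The deposited values are log2 intensities per probe set made by the authors with RMA (robust multi-array average, which corrects background, puts all arrays on a common distribution by quantile normalisation and summarises the probes of a probe set), per the submitters' processing notes. The version and settings of RMA are not given in the sources used here, and the log2 scale was read from the values themselves, which ran from 3.25 to 15.45 with array medians of 7.08 to 7.16. Quantile normalisation removes differences in total signal between arrays, so a change shared by most genes would not be seen, and background signal compresses differences of weakly expressed genes, so folds of such genes are understated. Mouse host RNA in a xenograft could hybridise to some probe sets, and its share was not given in the sources used here. All columns of the value table were matched to samples by name.

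Probe sets were named through the platform annotation, in which 41091 had 1 gene, 1801 had several and 11721 had none listed, besides 62 control probe sets. Entrez identifiers of 41037 probe sets matched a RefSeq gene table, which changed 0 symbols. Probe sets with 1 gene were kept, and each of 19775 genes was represented by its probe set with the highest mean over all arrays, a choice that mattered for the 10523 genes with more than 1 probe set. Among the 24 genes with the largest differences in each comparison, 15 had further probe sets, and in all 15 at least 1 of these differed from the main probe set by over 1 on the log2 scale, in no case with an opposite difference of over 0.5. Of 470 entries in 20 gene lists, 422 were measured; other entries, among them genes of androgen signalling and neural fate, are not reported here. Genes on the Y chromosome and genes of X inactivation were never named.

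Samples were grouped by line from their titles. Lines with the same number before the hyphen were taken as 1 origin. In the class comparison arrays were averaged per line and lines per origin, and 3 adenocarcinoma origins (79, 117 and 130) were set against 3 neuroendocrine origins (144 with lines 144-4 and 144-13, 146 with line 146-10, and 155 with line 155-12). Line 155-2 was left out because the design text of the series does not list it on either side. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over 19775 genes and a threshold of 0.05. In the comparison of 144-13 with 144-4, line was a factor over all 22 arrays, so that all lines shared 1 estimate of the spread between arrays. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation. With an estimated correlation camera also uses only the residual degrees of freedom of the fit. These were 4 between the classes and 14 in the fit over all arrays, so a lost call need not come from correlated genes. The fry test, which asks whether the genes of a list move on balance in 1 direction, was run beside it. Counts of list members past the threshold are given over all genes and adjusted over the list alone. Lines 155-2 and 155-12 were compared by values only, with list medians placed among 10000 random lists matched on mean expression.

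Apart from genes said to be singled out after their values were seen, among them PECAM1 and COL1A1, genes named in the text follow a rule. The rule was fixed before the data were examined. For each of both tested comparisons it takes the 12 genes with the largest difference in each direction among genes past the threshold without overlap between the sides, up to 4 members of each list (those past the threshold with the largest difference, otherwise those with the smallest p), and a set of key genes that includes RB1, CCND1, UBE2C and AURKA, which were chosen because the study of these tumours is known to concern them. Between 155-2 and 155-12 the 5 largest differences each way were taken among genes whose mean over all arrays was above the median gene. Errors are SDs over origins in the class comparison and over arrays in the comparison of 144-13 with 144-4, or standard errors of a difference where stated.

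The procedure was tested on simulated data with the real gene means and spreads and 200 changed genes. In the class comparison 31.6% of genes changed by 1 on the log2 scale, 64.4% of those changed by 2 and 87.1% of those changed by 4 were recovered, with 10 false calls (7.35% of calls), and in the comparison of 144-13 with 144-4 the shares were 91.2%, 97.3% and 100% with 0 false calls. Data without any change gave 0 calls in each comparison, and a mitosis list shifted by 1 was recovered with 0 of 19 other lists called. The simulated noise was independent between genes. The list result therefore does not cover lists whose genes vary together, such as interferon response in the class comparison (estimated correlation 0.60). Alternatives covered the replicate unit, the lines included, the summary of probe sets, a filter on dim genes, normalisation, the prior of eBayes, a minimum fold, replicate numbers as a block and the omission of each origin or array. Signs of RNA integrity were the 3' minus 5' differences of the actin and GAPDH control probe sets. Figures were drawn with matplotlib 3.10.9.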

Results

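Gene expression was measured on 22 oligonucleotide arrays of 8 human prostate cancer xenograft lines, tumours passaged under the skin of immunodeficient mice and named MDA PCa with a number. Each array carried probe sets, short probe groups near the 3' end of a transcript. Adenocarcinoma, the common gland-forming histology, was represented by lines 79 (3 arrays), 117-9 (3 arrays) and 130 (2 arrays). The neuroendocrine tumours comprised the large cell line 144-4 (5 arrays) and the small cell lines 144-13 (4 arrays), 146-10 (3 arrays), 155-2 (1 array) and 155-12 (1 array). For 144-4 and 144-13 the design text of the series gives 4 and 5 arrays, whereas the sample titles give 5 and 4. The titles were followed. Values lay between 3.25 and 15.45 on the log2 scale, and array medians between 7.08 and 7.16. Within each line with replicates, every array correlated best with its own line. The r ran from 0.81 to 0.98 over genes above the median gene, after subtraction of each gene's mean. No separate animals or cultures are named for the arrays of a line, so p-values over arrays measure only the spread between those arrays, which may be technical. The number of origins and arrays limited the precision of all values.

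The first comparison asked which genes separate tumours with small or large cell neuroendocrine features from adenocarcinomas, taking the origin (the number before the hyphen) as the replicate. Of 25 androgen-responsive genes 9 were lower and 16 did not pass the test in the neuroendocrine xenografts, whereas of 36 mitosis genes 20 were higher. KLK2, an androgen-regulated kallikrein protease of the prostate, had a level of 14.64 ± 0.08 in the adenocarcinomas and 7.23 ± 0.68 in the neuroendocrine tumours (log2, SD, n = 3 origins per class), a 171-fold difference (limma adjusted p = 0.00394). The cyclin gene CCND1, which drives entry into the cell cycle through the retinoblastoma protein, was 53.1-fold lower (11.71 ± 0.84 against 5.98 ± 0.35, adjusted p = 0.0142). AURKA, a kinase of the mitotic spindle, was 5.05-fold higher (9.38 ± 0.18 against 11.72 ± 0.04, adjusted p = 0.00497), and UBE2C, which marks mitotic proteins for degradation, was 5.69-fold higher (10.21 ± 0.38 against 12.72 ± 0.41, adjusted p = 0.0312).

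Of 19775 genes, 175 were higher and 109 lower in the neuroendocrine class, while 3009 had an unadjusted p under 0.05. The other genes with the largest decreases were STEAP2 (by 7.41 ± 0.29, log2 difference with its SE) and STEAP1 (by 6.85 ± 0.33). Both encode proteins of the prostate epithelial surface. They were followed by ACP3, which encodes prostatic acid phosphatase (a difference of -6.61 ± 0.46), the GTPase-activating gene ARHGAP6 (75.5-fold), the interleukin 1 receptor gene IL1R1 (48.0-fold) and the membrane serine protease gene TMPRSS2 (46.6-fold). SLC45A3, which encodes prostein, was 45.9-fold lower, CSGALNACT1, an enzyme of chondroitin sulfate synthesis, 43.4-fold, PMEPA1, an androgen-induced inhibitor of TGF-beta signalling, 37.1-fold, and PLA2G7, a secreted phospholipase, 36.0-fold. Among the genes that rose, the neuronal tubulin TUBB2B led with a difference of 6.83 ± 0.61, which is 114-fold. LDHB, a lactate dehydrogenase subunit, was 67.8-fold higher, and BAALC, a gene of neural and haematopoietic progenitors, 52.6-fold. SH3GL2, an endophilin of synaptic vesicle recycling, was 48.9-fold higher with little spread among the neuroendocrine origins (11.31 ± 0.04), and RNF182, a brain-enriched ubiquitin ligase, 40.3-fold. Further increases were found for INHBE, an inhibin subunit (34.1-fold), the microtubule-associated gene MAP1B (34.0-fold), the fucosyltransferase gene FUT9 (26.2-fold), the transcriptional corepressor RUNX1T1 (25-fold), CNRIP1, a cannabinoid receptor interacting protein (22.4-fold), the amino acid transporter SLC7A5 (21.2-fold) and the neuronal ubiquitin ligase TRIM9 (18.7-fold). These 24 genes were taken among those without overlap of the line means between the classes. Without arrays 2 and 5 of 144-4, which correlated least with their own line, FUT9 (a difference of 4.59, adjusted p = 0.0727) and IL1R1 (-5.51, adjusted p = 0.0548) did not pass. With the mean of all probe sets SLC45A3 differed by -4.01 (adjusted p = 0.0587). With line 155-2 included INHBE (adjusted p = 0.154), FUT9 (0.0596) and IL1R1 (0.0537) did not pass.

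**Figure D1:**
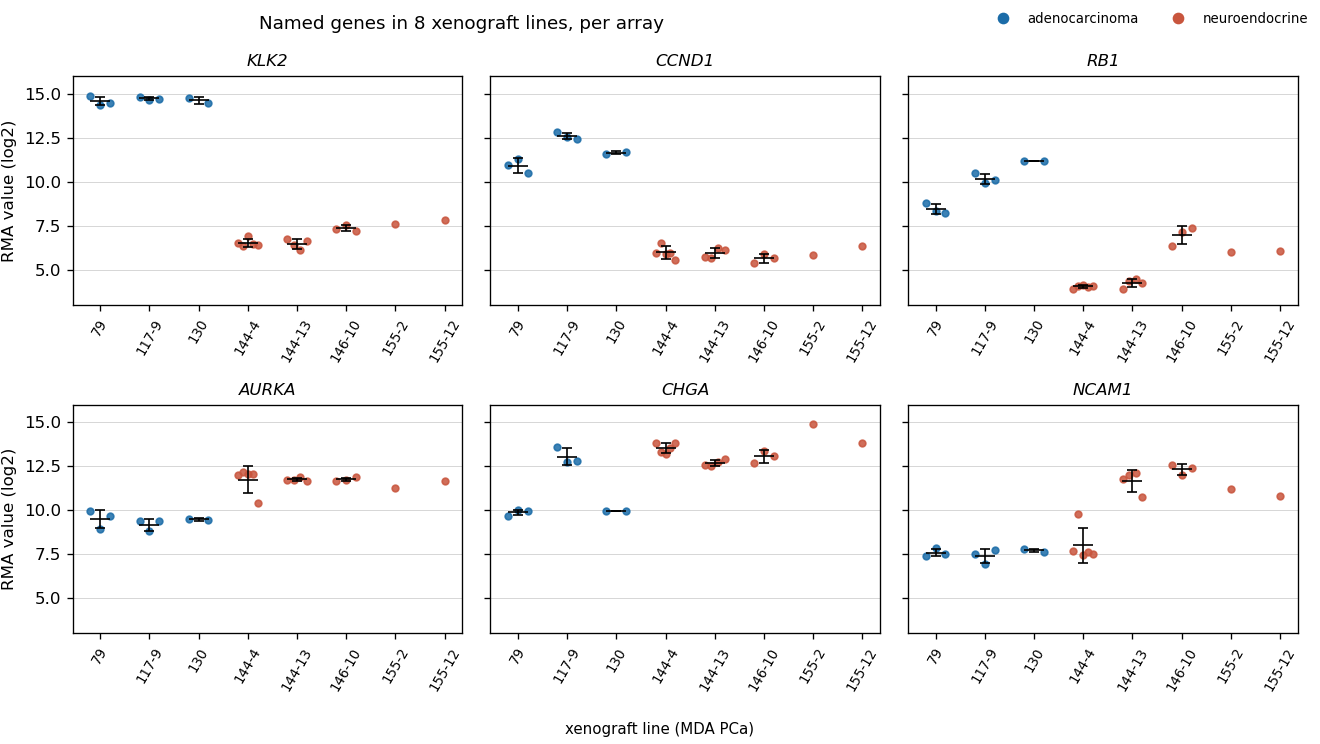
Log2 RMA value of 6 genes (y axis) on each array of the 8 xenograft lines (x axis), with blue points for adenocarcinoma and red points for neuroendocrine lines, and black bars for the line mean and SD where a line has more than 1 array. KLK2 and CCND1 sit above 10 in the adenocarcinoma lines and below 8 in the neuroendocrine lines, AURKA lies higher in the neuroendocrine lines, and CHGA is as high in adenocarcinoma line 117-9 (13.04) as in neuroendocrine line 146-10 (13.05).

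RB1, the retinoblastoma tumour suppressor, was 18.4-fold lower on average, at 9.93 ± 1.38 in adenocarcinomas and 5.73 ± 1.44 in neuroendocrine tumours. Its difference did not pass the test over origins (adjusted p = 0.137), although every neuroendocrine line mean lay below every adenocarcinoma line mean. The adenocarcinoma lines had means of 8.44, 10.17 and 11.18, and the neuroendocrine lines in the comparison had 4.05 (144-4), 4.25 (144-13), 6.96 (146-10) and 6.07 (155-12). Neuroendocrine markers were higher on average without passing the test. NCAM1, a neural adhesion molecule, was at 7.56 ± 0.16 and 10.99 ± 1.24 (adjusted p = 0.0868), and the synaptic vesicle protein gene SYP at 7.45 ± 0.45 and 8.59 ± 0.30 (adjusted p = 0.154). CHGA, the granule protein chromogranin A, was at 10.96 ± 1.80 and 13.32 ± 0.43 (adjusted p = 0.322). MYCN, a MYC family transcription factor, was at 7.01 ± 0.03 and 9.31 ± 1.77 (adjusted p = 0.315), EZH2, the polycomb methyltransferase, at 9.24 ± 0.46 and 11.04 ± 0.39 (adjusted p = 0.0784), and REST, a repressor of neuronal genes, at 9.16 ± 0.07 and 8.88 ± 0.07 (adjusted p = 0.261) by the probe set taken by the rule. With the mean of all its probe sets REST differed by -1.39 (adjusted p = 0.0170), a fall carried by 1 probe set (-3.68, adjusted p over all probe sets 0.0107). Some of these genes passed in single alternatives. NCAM1 passed with small cell lines only (adjusted p = 0.0224) and among genes above the median gene, where fewer genes are tested (0.0407). EZH2 passed there (0.0472) and with line means as replicates (0.0365). CHGA passed without origin 117 (a difference of 3.41, adjusted p = 0.0452), and MYCN without origin 155 (3.296, adjusted p = 0.0312). For KLK3, the gene of prostate-specific antigen, the probe set taken by the rule showed 10.36 ± 0.20 and 10.32 ± 0.10 (adjusted p = 0.928). Both other KLK3 probe sets differed by -5.89 and -7.36 (adjusted p over all probe sets 0.0367 and 0.0115).

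Among gene lists fixed before the data were examined, 11 of 20 were shifted between the classes by camera with its preset correlation of 0.01. With an estimated correlation, which also leaves fewer degrees of freedom, 2 of these 11 calls were left. The estimates for chromatin regulators (0.003) and HOX genes (0.001) were below the preset, so their lost calls do not come from a higher correlation. The fry test, which does not compare a list with other genes, called 8 of the 11 and 2 of the other 9 lists. The lists were chosen with prior knowledge that the study of these tumours concerned androgen signalling, RB1, CCND1, UBE2C and AURKA, so their directions are not independent evidence. Of 25 measured androgen-responsive genes 9 were lower and none higher (17 adjusted over the list alone), led by KLK2, ACP3, TMPRSS2 and SLC45A3, and 24 of 25 differences were negative. That list kept its call with an estimated correlation (adjusted p = 0.0383). Of 27 genes of luminal prostate identity 4 were lower (7 adjusted over the list alone), namely STEAP2, STEAP1, the pioneer transcription factor GATA2 (33.9-fold) and the homeobox gene HOXB13 (20.2-fold), with an adjusted p = 0.190 with an estimated correlation. Of 24 genes of steroid metabolism 1 was lower by either adjustment, the glucuronosyltransferase gene UGT2B15 (23.3-fold), and the list had an adjusted p = 0.221 with an estimated correlation. UGT2B15 differed by -4.54, and by -2.92 with the mean of all its probe sets (adjusted p = 0.0658). The call of the list was lost without origin 144 (adjusted p = 0.0592) or origin 155 (adjusted p = 0.0973), with line 155-2 included (0.0545) and among genes above the median gene (0.0619). In that list AKR1C3, an enzyme of androgen synthesis, was at 11.15 ± 2.18 and 6.58 ± 1.5 without passing the test.

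Proliferation genes made up the other large block. Of 36 mitosis genes 20 were higher and none lower (33 adjusted over the list alone), and all 36 differences were positive. CDC20, an activator of the anaphase-promoting complex, was 6.55-fold higher, NDC80, a kinetochore gene, 6.20-fold, the securin gene PTTG1 6.18-fold, and the mitotic kinesin KIF20A 5.97-fold. This list kept its call with an estimated correlation (camera adjusted p = 0.00500). That estimate, from 6 origins, was 0.013 and so near the preset, whereas between arrays of a line it was 0.64. The call therefore does not show that the list holds against strongly correlated genes. In the DNA replication list, 6 of 31 genes were higher (28 adjusted over the list alone) and all 31 differences were positive, with E2F8 (7.25-fold), cyclin CCNE2 (6.38-fold), the licensing factor CDT1 (3.05-fold) and the GINS subunit GINS1 (3.00-fold) in front. Its adjusted p = 0.0596 with an estimated correlation. With line 155-2 included NDC80 (adjusted p = 0.0552), KIF20A (0.0610) and GINS1 (0.107) did not pass. The 3' minus 5' difference of the GAPDH control probe sets, a sign of RNA integrity, averaged 1.22 ± 0.15 in adenocarcinomas and 0.99 ± 0.13 in neuroendocrine tumours. That of actin was 2.49 ± 0.32 and 2.36 ± 0.08 (log2, SD, n = 3 origins per class). Whether these measures differ between the classes was not tested. Among 21 chromatin and DNA methylation regulators, the maintenance methyltransferase DNMT1 (4.53-fold) and the heterochromatin protein CBX5 (2.51-fold) were higher (4 higher and 1 lower adjusted over the list alone), with an adjusted p = 0.0596 with an estimated correlation. With the mean of all probe sets CBX5 differed by 0.95 (adjusted p = 0.107), and with line 155-2 included CBX5 (0.0537) and DNMT1 (0.0637) did not pass.

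**Figure D2:**
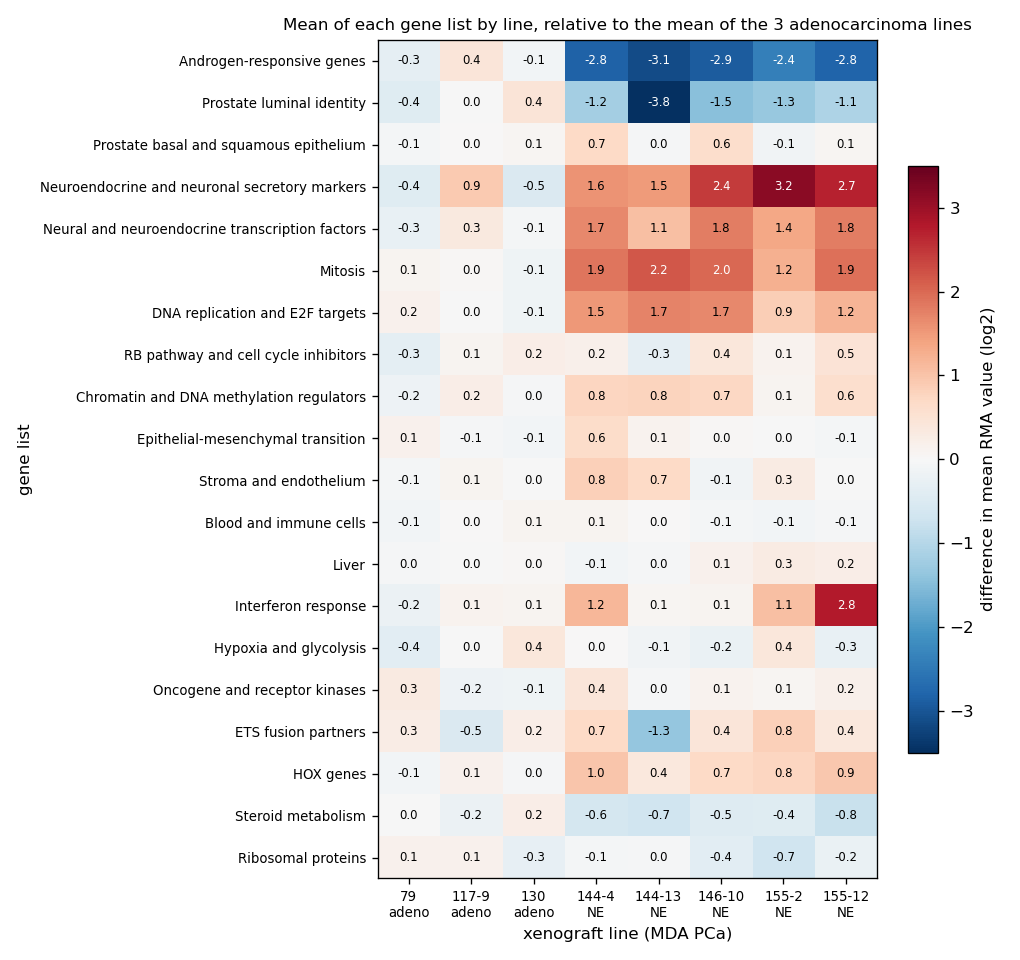
Mean log2 RMA value of the measured members of each of 20 gene lists (rows) in each xenograft line (columns, adenocarcinoma lines marked adeno and neuroendocrine lines NE), minus the mean of the 3 adenocarcinoma lines, with red for higher and blue for lower. The mitosis mean is 9.34 to 9.58 in the adenocarcinoma lines and 10.72 to 11.65 in the neuroendocrine lines, while the interferon mean of 11.55 stands out in line 155-12.

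By camera at the preset correlation 2 neural lists were also shifted upwards, with adjusted p = 0.171 (secretory markers) and 0.0596 (transcription factors) with an estimated correlation. None of 30 neuroendocrine and neuronal secretory markers passed the test over all genes (8 higher adjusted over the list alone), although 29 differences were positive. The synaptic gene RIMBP2 was at 6.24 ± 0.30 and 8.86 ± 0.87, the neuronal enolase ENO2 at 7.42 ± 1.5 and 12.13 ± 0.76, and the synaptic vesicle gene SV2A at 7.62 ± 0.09 and 10.41 ± 1.12. Of 32 neural transcription factors and regulators, the neuronal RNA-binding gene ELAVL4 was higher (11.4-fold; 6 genes adjusted over the list alone), and the Notch ligand DLL3 (7.74 ± 0.75 and 10.83 ± 0.80), LHX2 (6.12 ± 1.10 and 10.46 ± 1.17) and SOX2 (6.34 ± 0.96 and 11.03 ± 1.53), both transcription factors of the developing nervous system, did not pass. Among genes above the median gene ENO2 (adjusted p = 0.0357), DLL3 (0.0389), LHX2 (0.0397) and SOX2 (0.0428) passed. So did DLL3 with small cell lines only (0.0395), SOX2 with the large cell line alone for origin 144 (0.0205) and without origin 144 (0.0462), and SV2A without origin 144 (0.0489). Of 18 HOX genes HOXB13 was lower and HOXD11 higher (3.24-fold; 5 higher and 2 lower adjusted over the list alone), with HOXD8 at 7.68 ± 0.13 and 10.32 ± 0.78 and HOXD4 at 7.38 ± 0.05 and 8.74 ± 0.47, and an adjusted p = 0.0969 with an estimated correlation. HOXD11 did not pass without arrays 2 and 5 of 144-4 (adjusted p = 0.0526). HOXD8 passed among genes above the median gene (0.0293), with small cell lines only (0.0222) and without origin 144 (0.0394), and HOXD4 without origin 144 (0.0264). Among genes above the median gene the HOX list was not called (0.454).

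None of 21 interferon response genes passed by either adjustment, although the list was shifted upwards by camera, with an adjusted p = 0.706 with an estimated correlation. Its mean was 11.55 in line 155-12 and 9.95 in line 144-4, but 8.85 in 144-13 and 8.87 in 146-10, within the 8.58 to 8.90 of the adenocarcinoma lines, and without origin 155 the camera call was lost (adjusted p = 0.431). The most shifted members by p were the interferon regulatory factors IRF1 (7.79 ± 0.26 and 9.40 ± 1.00) and IRF7 (9.71 ± 0.69 and 10.64 ± 0.52), the antiviral gene OAS3 (8.74 ± 0.70 and 10.41 ± 1.13) and the immunoproteasome subunit PSMB9 (8.33 ± 1.21 and 10.14 ± 0.98). IRF1 passed without origin 144 (adjusted p = 0.0332). The 15 ribosomal protein genes were shifted slightly downwards, by 0.21 in the median, with none past the test by either adjustment and an adjusted p = 0.731 with an estimated correlation. That call was also lost without origin 79 (adjusted p = 0.251), 117 (0.159) or 146 (0.199), after renewed quantile normalisation (0.233) and among genes above the median gene (0.0953). RPL10A was at 15.12 ± 0.05 and 14.85 ± 0.17 and RPL3 at 14.56 ± 0.21 and 14.04 ± 0.39.

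The remaining 9 lists were not shifted by camera, though with each array centred on its median the RB pathway list was (adjusted p = 0.0386). In the list of 16 RB pathway genes and cell cycle inhibitors CCND1 was lower, and the cyclin-dependent kinase inhibitor genes CDKN2A (8.27-fold) and CDKN2B (7.11-fold) were higher (2 higher and 3 lower adjusted over the list alone), while RBL2, a relative of RB1, was at 11.40 ± 0.40 and 10.11 ± 0.26. Of 6 ETS and related fusion genes the transcription factor ETV5 was higher (9.07-fold, the same by either adjustment), and ETV4 was at 7.58 ± 0.02 and 8.77 ± 0.81. None of 22 oncogenes and receptor kinases passed (1 higher adjusted over the list alone); the SRC family kinase FYN was at 8.49 ± 0.51 and 11.56 ± 0.90, EGFR, the epidermal growth factor receptor, at 10.86 ± 0.26 and 8.81 ± 0.82, and MET, the hepatocyte growth factor receptor, at 7.10 ± 1.51 and 10.62 ± 0.99. FYN passed among genes above the median gene (adjusted p = 0.0344). By either adjustment no gene passed among 11 genes of basal and squamous epithelium, 16 of epithelial-mesenchymal transition, 22 of stroma and endothelium, 17 of blood and immune cells, 15 of liver and 17 of hypoxia and glycolysis. In these lists the keratin gene KRT15 was at 5.52 ± 0.24 and 7.43 ± 1.81, the transcription factor ZEB1 at 5.37 ± 0.12 and 7.72 ± 1.63, the fibroblast marker THY1 at 7.61 ± 0.04 and 7.36 ± 0.05, the haemoglobin gene HBB at 10.63 ± 0.14 and 10.35 ± 0.14, the antiprotease gene SERPINA1 at 7.60 ± 0.80 and 10.08 ± 2.76, and LDHA, a lactate dehydrogenase subunit, at 13.70 ± 0.28 and 14.27 ± 0.29. The ETS median (-0.07) and mean (0.16) differed in sign, and the liver list had a positive median (0.01) and mean (0.10) with a downward camera direction.

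The counts depended on each origin. Without origin 79 the numbers of higher and lower genes were 31 and 23, without 117 they were 67 and 50, without 130 they were 42 and 48, without 144 they were 164 and 68, without 146 they were 50 and 26, and without 155 they were 101 and 59. Of the 44 named genes past the test 13 passed in all 6 of these settings (KLK2, STEAP1, STEAP2, TMPRSS2, ARHGAP6, PLA2G7, GATA2, HOXB13, SH3GL2, RUNX1T1, AURKA, PTTG1 and CDKN2B). At the other end CDKN2A, DNMT1, GINS1, KIF20A and NDC80 passed in 0 of the 6 settings, and UBE2C in 1 (highest limma adjusted p = 0.104). In the other alternatives 29 of the 44 passed every time. The rest failed in at least 1, namely TUBB2B, INHBE, FUT9, RUNX1T1, IL1R1, SLC45A3, UGT2B15, NDC80, KIF20A, GINS1, DNMT1, CBX5, ELAVL4, ETV5 and HOXD11. Of 60 named genes that did not pass, 40 passed in at least 1 of these alternatives, nearly all of them with arrays taken as independent.

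The second comparison set the small cell line 144-13 against the large cell neuroendocrine line 144-4, which share an origin number. Both lines had a low level of RB1 (4.05 ± 0.09 in 144-4 and 4.25 ± 0.24 in 144-13, SD, n = 5 and 4 arrays, limma adjusted p = 0.388) and low CCND1 (5.98 ± 0.36 and 5.94 ± 0.29), yet they differed in a large part of the measured genes. MYC, a growth-promoting transcription factor, was 109-fold higher in 144-13 (6.0 ± 0.29 in 144-4 and 12.77 ± 0.13 in 144-13), whereas its relative MYCN was 7.17-fold lower (12.07 ± 0.14 and 9.22 ± 0.32). The epithelial genes EHF (a transcription factor, 167-fold), KRT19 (a keratin, 154-fold) and CDH1 (the adhesion molecule E-cadherin, 99.2-fold) were lower in 144-13, as was the stem cell transcription factor SOX2 (122-fold).

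Of 19775 genes, 4562 were higher and 4063 lower in 144-13 (52.9% of calls higher); with each array centred on its median the counts were 6333 and 3536 (64.2% higher). In the same fit lines 144-4 and 146-10, of different origins, differed in 8574 genes. With a difference of at least 2-fold required as well between 144-13 and 144-4, 1345 were higher and 1702 lower in 144-13. The largest increases were in EDIL3, a secreted integrin ligand (429-fold), ZFPM2, a cofactor of GATA factors (415-fold), the proteoglycan LUM (344-fold), the iron exporter SLC40A1 (317-fold) and DMD, the dystrophin gene (148-fold). After MYC came MPPED2, a metallophosphoesterase (91.0-fold), OTX2, a homeobox factor of the anterior brain (89.0-fold), the neuroendocrine zinc finger gene INSM2 (75.4-fold), PLPPR4, a phospholipid phosphatase relative of neurons (70.5-fold), the transcription factor SOX7 (69.0-fold) and the fatty acid transporter SLC27A6 (66.8-fold). The largest decreases were in the neuropeptide neurotensin (NTS, 346-fold), the neuronal microtubule gene MAP2 (200-fold), PDK4, a kinase that inhibits pyruvate dehydrogenase (187-fold), and STXBP6, a SNARE-binding protein (171-fold). After EHF and KRT19 they continued with the vesicular glutamate transporter SLC17A6 (148-fold), the transcription factor ZIC2 (135-fold), the matricellular gene CCN3 (132-fold), the phosphatase inhibitor PPP1R17 (129-fold), SOX2 and the matrix glycoprotein SPARCL1 (118-fold). All 24 of these genes had adjusted p-values of 2.49e-10 or lower, and they were taken among genes without overlap of the arrays of both lines.

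**Figure D3:**
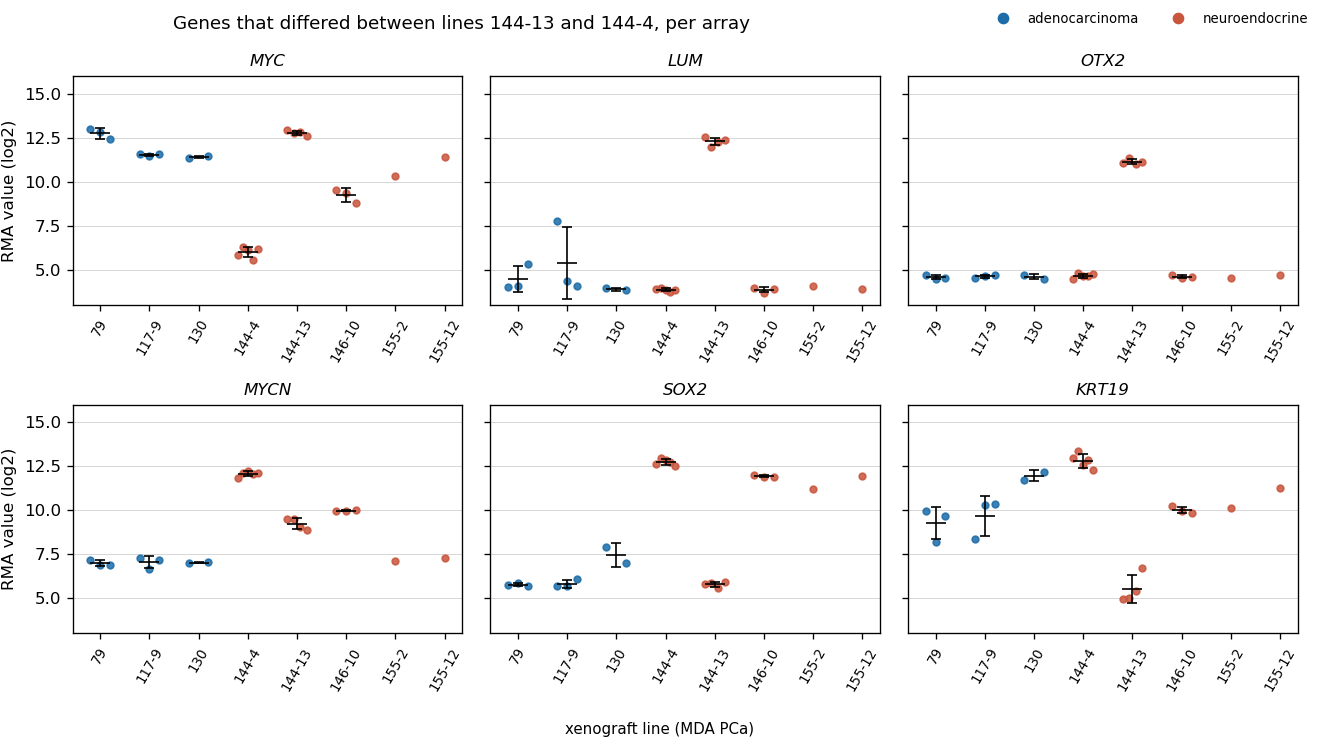
Log2 RMA value of 6 genes (y axis) on each array of the 8 xenograft lines (x axis), with blue points for adenocarcinoma and red points for neuroendocrine lines, and black bars for the line mean and SD where a line has more than 1 array. MYC has a mean of 6.0 in line 144-4 and 9.24 or more in each other line, LUM and OTX2 exceed 11 in line 144-13 alone, and KRT19 is lowest in line 144-13.

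Of the key genes, NCAM1 was 12.7-fold higher in 144-13 (8.01 ± 1.01 and 11.68 ± 0.63, adjusted p = 4.89e-07) and CHGA 1.83-fold lower (13.53 ± 0.29 and 12.66 ± 0.18, adjusted p = 0.000772). UBE2C (12.32 ± 0.49 and 12.21 ± 0.12), AURKA (11.74 ± 0.75 and 11.75 ± 0.10), EZH2 (11.38 ± 0.11 and 11.51 ± 0.09), SYP (8.49 ± 0.26 and 8.89 ± 0.16) and REST (8.93 ± 0.07 and 8.98 ± 0.16) did not pass the test. With the mean of all its probe sets REST differed by -0.33 (adjusted p = 0.0139), the opposite direction, which came from the same single probe set (-1.05). With replicate numbers as a block, a fit without array 5 of 144-4, AURKA (-0.321, adjusted p = 0.0341) and UBE2C (-0.327, adjusted p = 0.0299) were lower in 144-13. Omission of that array alone, on which both genes were low, gave the same differences without passing (adjusted p = 0.140 and 0.290). SYP passed after renewed quantile normalisation (adjusted p = 0.0262), with each array centred on its median (0.0378), with the 9 arrays of both lines alone (0.0428) and without array 1 of 144-4 (0.0379). The KLK3 probe set taken by the rule was 1.45-fold higher, whereas its other probe sets did not pass (0.23 and 0.11 higher on the log2 scale).

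By camera 4 of 20 lists were shifted, all downwards in 144-13. Of 27 luminal genes 20 were lower and 1 higher (the same adjusted over the list alone), with EHF, KRT19, CDH1 and the trefoil factor TFF3 (63.1-fold) in front, and this list alone kept its call with an estimated correlation (adjusted p = 0.00954). Of 21 interferon response genes 15 were lower and none higher (16 lower adjusted over the list alone), among them IFI44L (6.22-fold), the antiviral GTPase MX1 (5.36-fold), IRF7 (4.02-fold) and IFI27 (3.48-fold), with an adjusted p = 0.647 with an estimated correlation. IFI27 differed by -1.80, and by -0.79 without arrays 2 and 5 of 144-4 (adjusted p = 0.0726). The list mean was highest on arrays 2 and 5 of 144-4 (10.42 and 10.50, with 9.41 to 9.80 on the other 3), and array 4 of 144-13 (9.42) lay above array 1 of 144-4, so the lines overlapped. Without arrays 2 and 5 of 144-4 the list had 12 genes lower, a mean difference of -0.76 and a camera adjusted p = 0.00453, but 0.941 with an estimated correlation. In that setting IFI44L was 3.70-fold and MX1 3.25-fold lower, and without array 4 of 144-13 MX1 was 8.14-fold lower. Of 22 oncogenes and receptor kinases 12 were lower and 4 higher (12 and 5 adjusted over the list alone). The neuregulin receptor ERBB3 (18.1-fold) and the stem cell factor receptor KIT (15.9-fold) were lower, whereas MYC and MET (65.8-fold) were higher, and without array 2 of 144-4 the fold of MET was 116.3. The list had an adjusted p = 0.0578 with an estimated correlation and 0.0524 without arrays 2 and 5 of 144-4. Of 6 ETS and related fusion genes ETV1 (49.0-fold), ETV5 (33.8-fold) and ETV4 (2.61-fold) were lower, the same by either adjustment, with an adjusted p = 0.0580 with an estimated correlation.

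The other 16 lists were not shifted by camera, and most held genes that moved both ways. By fry 8 of these 16 passed. They were neural transcription factors (adjusted p = 2.51e-05), basal epithelium and HOX genes (each 0.000383), RB pathway (0.00249) and epithelial-mesenchymal transition (0.0412) downwards. Upwards were DNA replication (0.0156), ribosomal proteins (0.0386) and secretory markers (0.0412). The 4 lists called by camera also passed by fry. Without arrays 2 and 5 of 144-4 epithelial-mesenchymal transition (adjusted p = 0.102) and ribosomal proteins (0.0863) did not pass by fry. Androgen-responsive genes (0.0126), downwards, and chromatin regulators (0.0372), upwards, then did. So did stroma and endothelium (7.13e-05), downwards by fry although 13 of its 22 differences were positive, with a mean of 0.02. Stroma and endothelium had 4 higher and 4 lower of 22 genes by either adjustment, with LUM higher and the endothelial cadherin CDH5 (89.6-fold), the matrix protein POSTN (29.0-fold) and the collagen chain COL1A2 (24.5-fold) lower. By the probe set taken by the rule PECAM1 did not pass and COL1A1 was 0.24 higher, one of the 4, but other probe sets of PECAM1 and COL1A1 fell by 3.44 and 3.65. Without array 5 of 144-4 POSTN was 18.2-fold lower. Neuroendocrine secretory markers had 11 higher and 9 lower of 30 (12 and 10 adjusted over the list alone), with the granin SCG2 (29.0-fold), the monoamine transporter SLC18A1 (10.9-fold) and somatostatin (SST, 5.80-fold) lower. SST was 3.45-fold lower without array 1 of 144-4, where it did not pass (adjusted p = 0.0507), and 9.78-fold without array 5. Neural transcription factors had 11 higher and 10 lower of 32 (13 and 10 adjusted over the list alone), with the Notch effector HES1 (46.8-fold), NKX2-2 (17.5-fold) and ASCL2 (17.5-fold, and 28.8-fold without array 5 of 144-4) lower. HOX genes had 5 higher and 8 lower of 18 (6 and 8 adjusted over the list alone), with HOXB6 (21.6-fold), HOXB2 (5.73-fold), HOXB9 (4.72-fold) and HOXB5 (3.29-fold) lower. Mitosis genes had 15 higher and 3 lower of 36 by either adjustment, with BIRC5, the survivin gene (2.89-fold), and the spindle checkpoint gene MAD2L1 (2.32-fold) higher. DNA replication genes had 14 higher and 5 lower of 31 (16 and 5 adjusted over the list alone), with the cyclin CCNE1 (2.87-fold) lower and thymidylate synthase (TYMS, 2.21-fold) higher. RB pathway genes had 2 higher and 6 lower of 16 by either adjustment, with the cell cycle inhibitors CDKN1A (10.8-fold) and CDKN1C (5.17-fold) lower. Epithelial-mesenchymal transition genes had 2 higher and 6 lower of 16 by either adjustment, with vimentin (VIM, 5.62-fold) and TWIST1 (4.78-fold) lower. The mean of that list was 8.72 and 8.75 on arrays 2 and 5 of 144-4 and 7.86 to 8.10 on the other 3, against 7.62 to 7.95 in 144-13.

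Basal and squamous epithelium had 0 higher and 5 lower of 11 genes (6 lower adjusted over the list alone), with KRT15 (8.32-fold) and S100A2 (5.24-fold) lower. Androgen-responsive genes had 6 higher and 7 lower of 25, with the elongation factor ELL2 (23.6-fold) lower and the efflux pump ABCC4 (2.92-fold) higher. Hypoxia and glycolysis genes had 5 higher and 4 lower of 17, with adrenomedullin (ADM, 29.6-fold) and VEGFA (2.12-fold) lower and hexokinase HK2 higher (2.86-fold; adjusted p = 0.0184, and 0.0736 without arrays 2 and 5 of 144-4). Chromatin regulators had 7 higher and 2 lower of 21, with the deacetylase HDAC9 (5.41-fold) lower and the histone-binding gene RBBP4 (2.16-fold) higher. Steroid metabolism had 2 higher and 3 lower of 24, with AKR1C3 (7.08-fold) lower. Blood and immune genes had 1 higher and 2 lower of 17, liver genes 1 higher and 1 lower of 15, and ribosomal protein genes 4 higher and none lower of 15, with RPL8 1.48-fold higher. In these last 7 lists the counts were the same adjusted over the list alone. Median and mean differed in sign in the lists of secretory markers, neural transcription factors, blood and immune cells, hypoxia and glycolysis, and steroid metabolism.

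Each histology was a single line here, so line and histology could not be separated. The 3' minus 5' differences of the control probe sets as covariates left 3393 higher and 3243 lower genes, and 10 of the 98 named genes past the test then did not pass. Their differences before and after were -0.87 ± 0.18 and -0.69 ± 0.28 for CHGA, -0.48 ± 0.19 and -0.43 ± 0.29 for LAMB3, and -1.12 ± 0.36 and -1.23 ± 0.57 for CDK6. They were -0.65 ± 0.19 and -0.56 ± 0.21 for SRD5A1, 0.21 ± 0.07 and 0.24 ± 0.11 for CSF1R, and 1.04 ± 0.22 and 0.82 ± 0.34 for PDK1 (SE). For MMP2 they were -1.53 ± 0.31 and -0.91 ± 0.44, and for IFI27 -1.80 ± 0.58 and -0.84 ± 0.83. HK2 had 1.52 ± 0.49 and 0.75 ± 0.67, and NR3C1 1.25 ± 0.34 and 0.63 ± 0.48. Leaving aside omission of single arrays, 83 of the 98 passed in every alternative. Besides these 10, KLK3, RPL7, S100A8, SST and TRIM29 failed in at least 1. With single arrays left out LAMB3, SST, CSF1R and HK2 did not pass in at least 1 case.

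Lines 155-2 and 155-12 share an origin number and had 1 array each, so their difference has no replicate check and values alone are given. NPTX2, a secreted synaptic pentraxin, was 20.1-fold higher in 155-2 (10.13 against 5.80), followed by PCCA, a subunit of propionyl-CoA carboxylase (15.3-fold), the orphan nuclear receptor RORB (15.3-fold), the protein kinase A inhibitor PKIB (13.5-fold) and the scaffold protein AKAP12 (11-fold). NTS was 23.8-fold lower in 155-2 (8.99 against 13.57), followed by the small secreted protein MUCL1 (23.7-fold), the N-acetyltransferase subunit NAA16 (17.3-fold), the secreted neural protein NELL2 (17.0-fold) and the signalling gene SMAD9 (16.9-fold). In all, 1411 genes differed at least 2-fold between these arrays, against 3062 between the means of 144-13 and 144-4.

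In 155-2 the mitosis mean was 10.72 against 11.42 in 155-12, with 34 of 36 genes lower, and the interferon mean was 9.84 against 11.55, with 15 of 21 genes lower. Neuroendocrine secretory markers were higher in 155-2 in 22 of 30 genes (mean 10.84 against 10.39), and all 17 hypoxia and glycolysis genes were higher (11.66 against 11). As a description of these arrays, the list medians were set against 10000 random lists of the same size matched on mean expression. Genes that vary together reach extreme percentiles more easily than random genes. Between arrays of a line the estimated correlation was 0.64 for mitosis and 0.52 for interferon genes, so the percentiles do not measure how sure a shift is. Mitosis and interferon lay at percentile 0, chromatin regulators at 0.03, RB pathway at 0.13, DNA replication at 0.23, ribosomal proteins at 0.35 and neural transcription factors at 1.39. Steroid metabolism lay at 97.6, ETS genes at 98.5, hypoxia and glycolysis at 99.98 and secretory markers at 100, and the other 9 lists between 14.5 and 96.3.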

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

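Of the tests in this part, those for a wrong label, for host cells and for RNA quality (the 3' minus 5' covariates) between 144-13 and 144-4, for the KLK3 probe sets and for the place of line 155-2 were chosen after the result was seen. Line 155-2 took no part in the class comparison, and it lay beyond all 3 adenocarcinoma lines on the neuroendocrine side in 278 of the 284 genes called there (97.9%). Among the 19491 genes not called the share beyond all 3 lines on the side of the difference was 48.0%. The called genes were selected for their difference from these same 3 lines, so the 48.0% is no measure of what chance would give. Line 155-2 shares its origin number with line 155-12, so this is no independent replicate.

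A gap test for single arrays that stand apart from their line was run on 414 values of named genes, list means and technical measures in the 5 arrays of 144-4 and the 4 arrays of 144-13. Chance alone marks about 1 in 20 such groups, and here 34 of 414 were marked. Array 2 of 144-4 accounted for 9 of them. On it FUT9 was at 8.38 (4.66 to 5.00 on the other arrays of the line), NCAM1 at 9.80 (7.45 to 7.66), MET at 10.08 (5.80 to 6.29), HOXD11 at 9.89 (7.89 to 8.32) and SLC40A1 at 6.57 (4.60 to 5.10). PLPPR4 was at 6.66 (5.11 to 5.54), SOX7 at 7.27 (5.45 to 5.91), ABCC4 at 8.07 (7.49 to 7.55) and CDK6 at 9.29 (7.49 to 7.76). All 9 marks were upward. In 7 of these 9 genes the array lay towards the mean of 144-13, and 7 of the 9 were higher in 144-13 by the test. SLC40A1, PLPPR4 and SOX7 were named because they were far higher in 144-13, so this direction was partly set by the choice of genes. Array 5 of 144-4 was low in UBE2C (11.47 against 12.35 or more), AURKA (10.40 against 12.00 or more), ETV5 (12.08 against 12.59 or more), LDHA (14.47 against 14.65 or more) and ASCL2 (7.66 against 10.89 or more), and high in OAS3 (11.14 against 10.06 or less). Array 1 of 144-4 was low in KLK3 (9.95 against 10.15 or more) and high in IRF7 (11.45 against 11.08 or less) and ERBB3 (11.47 against 10.73 or less), and array 3 was low in THY1 (7.10 against 7.37 or more).

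Array 4 of 144-13 accounted for 12 marks. It was high in the interferon list mean (9.42, with the other arrays at 8.63 to 8.69), OAS3 (9.92 against 9.06 or less), PSMB9 (10.12 against 9.02 or less), IRF7 (10.13 against 8.90 or less) and CDC20 (13.40 against 12.73 or less). It was low in SH3GL2 (10.48 against 11.39 or more), ZEB1 (9.43 against 10.10 or more), MET (12.04 against 13.05 or more), EDIL3 (13.46 against 14.11 or more), SLC40A1 (12.73 against 13.70 or more), PLPPR4 (11.38 against 11.83 or more) and SLC27A6 (9.75 against 11.16 or more). Array 3 of 144-13 was high in GINS1 (11.67 against 11.60 or less) and LYZ (7.15 against 6.71 or less) and low in ADM (5.72 against 6.65 or more).

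Mitosis genes were higher in the neuroendocrine class by 1.99 on average (log2). Within lines the slope of the mitosis mean on the 3' minus 5' signal was uncertain (-0.19 ± 0.38 for actin and 0.11 ± 0.30 for GAPDH, SE). The classes differed little in these measures (-0.13 and -0.23), so the predicted shift had an upper 95% bound of 0.136. This argues against RNA quality, as far as these probe sets measure it, as the cause. The bound takes the class differences of the measures as known without error. The central 95% of random lists matched on mean expression ended at 0.330, which argues against a drift with intensity left by normalisation. Of the 10 splits of the 6 origins 1, the real one, gave as many genes (284, with 1 gene in the highest other split), but 10 splits are too few for a share under 0.05. A faster cell cycle in tumours of the neuroendocrine class may explain the shift, a hypothesis that was not tested apart from other differences between the origins.

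Lines 144-13 and 144-4 differed in 8625 genes despite a shared origin number. Over genes above the median gene, after subtraction of each gene's mean, the r between their line means was 0.08. For lines 155-2 and 155-12 it was 0.57. In the same fit lines 146-10 and 144-4 differed in 8574 genes (r 0.002), and 146-10 and 144-13 in 8881 (r 0.01). Pairs of adenocarcinoma lines differed in 5729 to 6322 genes (r 0.27 to 0.42). These lines had 2 or 3 arrays against 3 to 5 here, and fewer arrays lower such a count. The subtracted mean covers more neuroendocrine than adenocarcinoma lines, so r cannot be compared between the classes. A count of this size is therefore not particular to this pair. A wrong label of single arrays is argued against, as 9 of 9 arrays correlated better with their own line. RNA quality as the main cause is argued against by the 6636 genes left with the 3' minus 5' covariates. Host cells in one line stay open for part of the difference, as 5 stroma and endothelium markers had a probe set over 1 higher in 144-4 (CDH5, COL1A2, POSTN and, by other probe sets than the main one, PECAM1 and COL1A1), while 3 were higher in 144-13 (LUM, DCN and COL5A1). Of 100 splits of the 9 arrays 1, the real one, gave as many genes (8625 against 6831 in the highest other split). As arrays of a line resemble each other, this shows only that the arrays group by line. It cannot decide whether 2 single lines differ by chance. Host cells, a difference of histology, or anything else between whole lines such as passage or tumour site, may explain the rest, which was not tested further.

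KLK3 was flat between the classes by the probe set with the highest mean (means from 10.08 to 10.67 over the lines). Both other probe sets were lower in the neuroendocrine class, with differences of -5.89 and -7.36 and no overlap of the lines compared. A probe set that does not follow KLK3 transcripts may therefore explain the flat value. Averaging all its probe sets gave KLK3 an adjusted p of 0.0195.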

How the results depend on the processing

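Alternatives without arrays 2 and 5 of 144-4, with 3' minus 5' covariates and with the list test on brighter genes were chosen after seeing the data. No named gene or list past the threshold changed direction under the alternatives run for it, and 29 changes of sign passed in neither setting. Other genes were not checked for direction. Between 144-13 and 144-4, 2 results past the threshold only in an alternative had the opposite direction there: REST with the mean of all probe sets (0.0507 in the main analysis, then -0.333, adjusted p = 0.0139) and AURKA with the replicate block (0.0150, then -0.321, adjusted p = 0.0341). REST moved through 1 of its other probe sets (-1.05), and AURKA through array 5 of 144-4, which the block fit leaves out and on which AURKA was low (10.40 against 12.00 or more): without that array alone the difference was also -0.321. The class counts (175 higher, 109 lower) rose to 1123 and 1032 with single arrays and origin as a random block. That fit used 1 correlation of 0.47 for all genes and so counted arrays of an origin as partly independent. With arrays taken as independent, which by construction counts arrays of a line as separate tumours, the class counts rose to 2908 and 2766. They ranged from 31 to 164 higher and from 23 to 68 lower when each origin was left out in turn, which leaves fewer samples. With line 155-2 included 112 were higher, of which 103 were among the 175, and 93 lower; the cause was not tested. Line means, small cell lines only, the large cell line alone for origin 144, probe set means, brighter genes, both scalings, a trend prior, a 2-fold minimum and omission of arrays 2 and 5 of 144-4 gave 139 to 214 higher and 84 to 158 lower. In the comparison of 144-13 with 144-4, a 2-fold minimum left 1345 higher and 1702 lower, and restriction to genes above the median gene, which tests fewer genes, left 3004 higher and 3012 lower; leaving out single arrays gave 4117 to 4525 higher and 3687 to 4082 lower, and omission of arrays 2 and 5 of 144-4 gave 4278 and 4053. Replicate numbers shared by these lines did not pair the arrays (correlations of deviations -0.06, 0.19, 0.05 and 0.08 for numbers 1 to 4, with a higher correlation to another number for 1 and 3), and with them as a replicate block 3833 genes were higher and 3765 lower in 8 arrays (7598 in all, against 8037 without the block). With an estimated correlation, and so fewer degrees of freedom, 2 of 11 list calls between the classes were left (androgen-responsive genes and mitosis). Between 144-13 and 144-4, 1 of 4 was left (luminal identity). In the other alternatives 8 to 12 and 3 to 4 lists were called. Genes near the lower end of the scale have folds compressed by background.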

Other observations

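The test of line 117-9 was chosen after its values were seen. Adenocarcinoma line 117-9 carried several neuroendocrine secretory genes at higher levels than the other adenocarcinoma lines. Against the mean of lines 79 and 130, 16 of 30 markers were higher and 2 lower (limma, line as factor over all arrays), and the list was shifted by camera (adjusted p = 2.63e-05, and adjusted p = 0.0227 with an estimated correlation). The synaptotagmin gene SYT4 was at 13.19 in 117-9, 6.63 in 79 and 6.22 in 130, and the exocytosis gene SNAP25 at 10.65, 5.34 and 5.68. The granin CHGB was at 9.53, 5.14 and 5.12, and SCG3, another granin, at 8.65, 4.25 and 4.39. These genes were singled out after their values were seen. A wider neuroendocrine programme in this line was tested as a hypothesis and stays open: neither the neural transcription factor list (mean difference 0.50, adjusted p = 0.105) nor the mitosis list (0.06, adjusted p = 0.790) passed the camera test, while by fry the transcription factor list was higher (8 genes higher, 3 lower, adjusted p = 0.00104) and the mitosis list did not pass (adjusted p = 0.895). The androgen-responsive list was higher in 117-9 than in 79 and 130 (13 of 25 genes higher, 2 lower, adjusted p = 0.000508, and adjusted p = 0.202 with an estimated correlation).

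In line 144-4 several genes of mesenchymal and vascular tissue were high. COL1A2 was at 14.12 against 9.21 to 10.69 in all other lines, CDH5 at 11.66 against 5.17 to 5.56, POSTN at 10.57 against 8.41 or less, SPARCL1 at 13.46 against 7.93 or less and VIM at 12.89 against 10.91 or less. COL1A1 and PECAM1 were nearly flat by the probe set with the highest mean. By others COL1A1 was at 9.11 in 144-4, 8.77 in 155-2 and 5.24 to 6.57 elsewhere, and PECAM1 at 10.77 in 144-4 and 6.90 to 7.83 elsewhere. The endothelial receptor gene KDR was at 5.98 in 144-4 and 5.38 to 5.67 elsewhere, and TEK at 7.36 and 7.19 to 7.42. In line 144-13 LUM (12.28), DCN (12.41) and COL5A1 (9.12) stood above all other lines (5.39, 8.44 and 7.34 or less), while the collagen gene COL3A1 was at 8.37 against 8.31 to 9.41 elsewhere. The source of these transcripts, tumour or host, was not tested. These genes were likewise singled out after their values were seen.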
